A study of Mus musculus with 90 samples.

How the data were processed

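RAW 264.7 cells, a mouse macrophage line, were treated with LPS at 100 ng/ml (listed with lipid binding protein at 100 pM), IFG at 5 nM, 2MA at 500 µM, LPS+IFG or LPS+2MA for 1, 2 or 4 h. RNA of each condition was hybridized with time-matched untreated RNA to custom Agilent oligonucleotide arrays, with 3 numbered sets per condition and both dye orientations in each set, giving 90 arrays. The labels do not say whether the sets were separate cultures, nor whether the treatments shared untreated RNA. If the sets were technical repeats, the p-values measure only the spread between these samples.

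The deposited values are log2 ratios of the channels of an array, which follows from the values: they are positive and negative, and 14 of them on 10 arrays lie exactly at the log2 of a 100-fold ratio (6.64), with none beyond it. How the images were read, background was handled and ratios were normalized by the authors is not given in the sources used here. Every array had a median of 0 over all probes. Exact zeros made up 7.84 to 17.0% of an array's values (median 9.41%) and were treated as missing, since 753 of 16281 probes were 0 on every array. Direction was taken as Cy5 over Cy3, so arrays with treated RNA in Cy3 had their sign turned. This is likely correct because 7 of 7 genes known to be raised by LPS (median 2.72) and 5 of 5 measured of 6 known for IFG (median 3.20) then had ratios above 0. Dye-swapped arrays of a set were negatively correlated across probes before turning in 37 of 45 pairs (-0.784 to 0.396) and, with each probe's mean over all arrays removed, in 45 of 45 (-0.925 to -0.169); genes are not independent replicates in these correlations.

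Of 13790 probes with an annotation entry, 13738 named a single gene, and 99.7% of their gene IDs were found in the reference gene table. A replicate was the mean of the dye-swapped arrays of a set. Probes with a value in at least 2 of 3 replicates of every condition were kept (13711), and probes of the same gene were averaged (1920 genes had several), which left 11600 features with 1.04% of replicate values missing. The number of arrays limits the precision. The residual SD of a replicate had a median of 0.199.

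A linear model with a mean for each of 15 conditions was fitted by least squares to the 45 replicates of each feature. R 4.3.3 was used, with at most 30 residual degrees of freedom. Variances were moderated with limma 3.58.1 (prior 5.8 degrees of freedom, prior SD 0.185), and the resulting moderated t-test is called limma's below. The 32 comparisons were each condition against 0 (15), each combination against LPS at the same time (6), each combination less the sum of its single treatments (6) and 4 h less 1 h within each treatment (5). P-values were two-sided and adjusted by Benjamini and Hochberg within a comparison. Figures and the reading of files used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Deviations of same-numbered sets correlated above 0.1 in 86 of 90 pairs of treatments at a time (median 0.433) and in all pairs of LPS with a combination (lowest 0.117). The sets therefore appear paired within a time for the combinations against LPS. They do for additivity as well, though less clearly at 2 h of LPS+IFG and at 1 h of LPS+2MA. There 8 of 9 pairs lay above 0.1 (lowest -0.031 in both, medians 0.438 and 0.354). The main fit does not use this pairing, so its SEs for these comparisons may be too large. A fit with the set as a block was run as an alternative. Sets of 4 h and 1 h did not pair. In another alternative, fitted to all 90 arrays with a dye term, the correlation between the dye-swapped arrays of a set was estimated as 0.271.

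Shifts of 27 gene lists were tested against all other features with camera on the moderated statistics, with a preset correlation of 0.01 and again with a correlation estimated from each list's residuals, adjusted over the 27 lists of a comparison. Of 864 tests, 298 were called with the preset and 172 of these held with the estimated correlation. The lists were inflammatory cytokines, chemokines, immediate early genes, NF-kB pathway and feedback regulators, interferon-stimulated antiviral genes, interferon-gamma response genes, antigen processing, MAPK phosphatases and Sprouty inhibitors, cyclic AMP and CREB response genes, purine receptors, eicosanoid synthesis, glycolysis and hypoxia, sterol and fatty acid synthesis, lipid efflux, cell cycle, growth arrest and p53 targets, unfolded protein response, oxidative stress, heat shock, apoptosis regulators, macrophage receptors, lysosomal hydrolases, markers of 4 other cell types, and reference genes. Some genes are on several lists. The lists, comparisons, thresholds, most alternatives and the rule for naming genes were chosen before the data were examined.

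Genes were named by a rule. For a treatment against control they were the 8 highest and 5 lowest called genes with the same sign on all 6 arrays at the time with most calls, and the 3 highest and 2 lowest at other times. For a combination against LPS and for additivity they were the 6 highest and 6 lowest at the time with most calls, without overlap of replicates in the former, and for 4 h less 1 h the 3 highest and 3 lowest. Added to these were the 4 called members of each list with the largest change, and Tnf, Il1b, Il6, Nos2, Ptgs2, Cxcl10, Irf1, Socs3, Fos and Egr1 in every comparison. Clone names were passed over, and Cxcl10 lacked the values to be tested.

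Simulated data of the same shape were made, with a dye bias in each feature whose spread was chosen by hand. The model was tested on them, with 50 of 11600 features changed at each fold. For LPS at 4 h it found 74, 98, 100 and 100% of features changed 1.5-, 2-, 3- and 4-fold by adjusted p, and 0, 52, 100 and 100% with the 2-fold minimum as well. For LPS+IFG against LPS at 4 h it found 52, 90, 98 and 98% by adjusted p, and for additivity of LPS+IFG at 4 h 30, 70, 98 and 100%. Of 200 random lists tested for LPS at 4 h, 1.5% had p under 0.05. The simulated features varied independently of each other, so this share does not check lists whose genes vary together. Sets were not paired between treatments in the simulated data either, so the effect of pairing on these rates was not checked. Alternatives were array median centring, scaling to equal spread, complete values, no filter on missing values, probes kept apart, either dye orientation alone, all 90 arrays with a dye term, fits to the compared conditions only, the set as a block and each replicate left out. Zeros kept as 0, and averaging before the filter, were added after the data were seen.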

Results

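RNA of RAW 264.7 cells, a mouse macrophage line, was compared with time-matched untreated RNA after 1, 2 or 4 h of treatment. The treatments were lipopolysaccharide (LPS), the cytokine interferon gamma (IFG), the ATP analogue 2-methyl-thio-ATP (2MA), LPS+IFG and LPS+2MA. The 90 dual-colour arrays made 45 replicates, each the mean of a dye-swapped pair of arrays, with 3 replicates in each of 15 conditions. Of the features on the array, 11600 entered every comparison: 9760 genes and 1840 probes without a gene name. A feature was called changed where limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05 and the mean ratio differed by at least 2-fold. Values are mean log2 ratios of treated over control RNA ± SD over 3 replicates unless another number is given. Differences between conditions are given with their standard error (SE). The labels do not state the direction of the ratio, so every direction is likely rather than known. Counts of list members adjusted over the list alone equalled those over all genes unless a second count is printed.

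LPS, a component of the outer membrane of Gram-negative bacteria sensed by Toll-like receptor 4, changed more features at each later time. At 1 h it changed 125 (119 higher, 6 lower), at 2 h 256 (213 higher, 43 lower) and at 4 h 558 (422 higher, 136 lower). The corresponding counts were 43, 125 and 216 with IFG, 39, 38 and 17 with 2MA, 215, 433 and 778 with LPS+IFG, and 142, 322 and 763 with LPS+2MA. With the spread of all arrays scaled to be equal, LPS lowered 19 features at 1 h and 62 at 4 h, LPS+IFG changed 474 at 4 h (364 higher, 110 lower) and IFG 74 at 1 h. With treated RNA in Cy5 alone LPS lowered 59, 89 and 262 at 1, 2 and 4 h. IFG changed 75 at 1 h on the arrays with treated RNA in Cy5 and 80 on those with it in Cy3. Each ratio was tested against 0, so the spread between untreated cultures enters only through the control RNA on the same arrays.

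**Figure D1:**
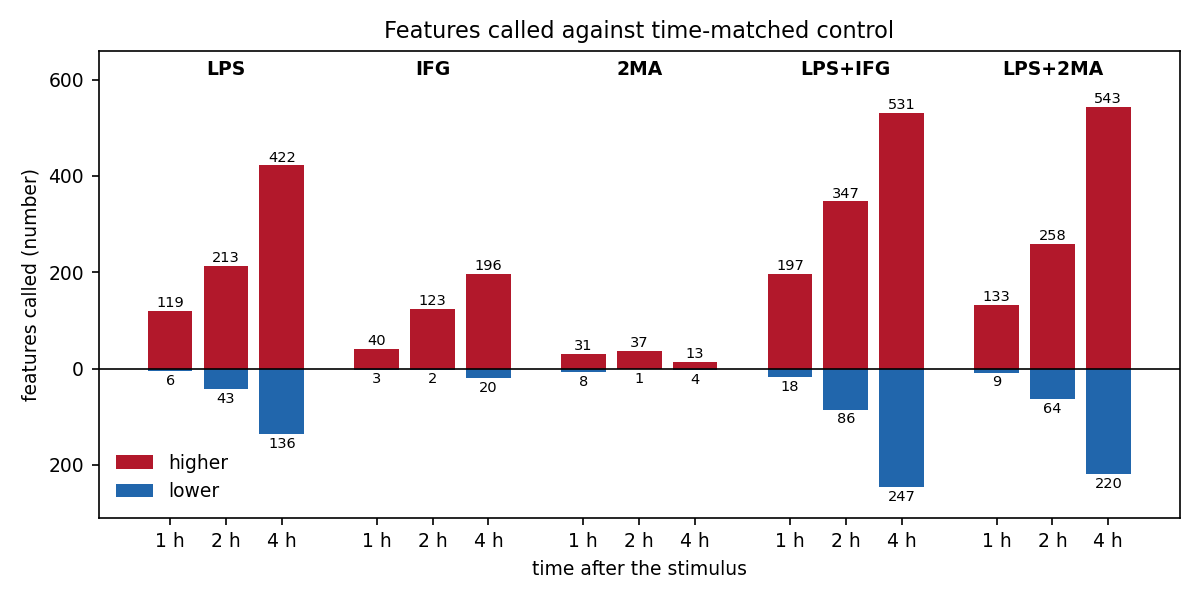
Number of features called against time-matched control RNA (y axis) in each treatment after 1, 2 and 4 h (x axis), with bars above 0 for higher and below 0 for lower features. LPS and both combinations had the most calls at 4 h, with 422 to 543 features higher and 136 to 247 lower, while 2MA had the fewest there.

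With LPS, Nfkbiz, which encodes an inducible nuclear partner of NF-kB, reached 5.04 ± 0.50 at 1 h, Phlda1 4.31 ± 0.36 and the immediate early factor Egr1 4.14 ± 1.22. These were the highest among called genes with the same sign on all 6 arrays. Of the measured immediate early genes, 21 of 31 rose at 1 h, among them Dusp1 at 3.94 ± 0.46 and Btg2 at 3.81 ± 0.62 (camera adjusted p = 2.81e-56). The NF-kB pathway and its feedback regulators had 12 of 23 members higher (adjusted p = 1.93e-40). The cyclic AMP and CREB response genes had 11 of 30 (adjusted p = 3.39e-20), including the phosphodiesterase gene Pde4b at 2.56 ± 0.29. Inflammatory cytokines rose in 7 of 21 cases (adjusted p = 4.86e-14), with Tnf at 3.44 ± 0.43 and Il1b at 2.90 ± 0.40. The prostaglandin synthase gene Ptgs2 stood at 1.67 ± 0.48, whereas Il6 (0.14 ± 0.21) and the nitric oxide synthase gene Nos2 (-0.02 ± 0.04) were not called before 2 h and 4 h respectively. Txnip, encoding a thioredoxin-binding protein, fell to -1.93 ± 0.32 and Sfi1 to -1.73 ± 0.31. Smaller groups rose too: 3 of 9 MAPK phosphatases and Sprouty inhibitors and 4 of 19 growth arrest and p53 targets (adjusted p = 1.38e-11 and 8.3e-06). So did 4 of 23 unfolded protein response genes, with Ppp1r15a at 2.05 ± 0.53, and 5 of 25 apoptosis regulators (adjusted p = 3.52e-06 and 1.31e-08).

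By 2 h Il1b had reached 4.58 ± 0.20, Il6 2.01 ± 0.42 and the interferon regulatory factor Irf1 2.29 ± 0.38, while the iron exporter Slc40a1 fell to -2.07 ± 0.71 and the sialyltransferase St8sia4 to -1.79 ± 0.23. Members of the NF-kB list rose in 15 of 23 cases, with Nfkbiz at 4.95 ± 0.14 and the adaptor Traf1 at 2.93 ± 0.19. At 4 h 32 of 35 interferon-stimulated antiviral genes rose (adjusted p = 1.27e-50), against 1 of 35 at 1 h, among them the nucleotide kinase Cmpk2 at 5.47 ± 0.29 and Ifit2 at 5.27 ± 0.33. Interferon-gamma response genes rose in 20 of 28 cases (adjusted p = 5.56e-28), with the guanylate-binding protein gene Gbp3 at 4.99 ± 0.53 and the co-stimulatory receptor Cd40 at 4.60 ± 0.44. The acute-phase gene Saa3 stood at 4.91 ± 0.13, Il6 at 4.50 ± 0.10, Nos2 at 3.02 ± 0.44 and Ccl4 at 3.84 ± 0.13. Inflammatory cytokines (14 of 21, adjusted p = 1.46e-16) and chemokines (5 of 16, adjusted p = 1.18e-07) were higher as groups. So were antigen processing genes (4 of 22, with the peptide transporter Tap1 at 2.12 ± 0.44, adjusted p = 4.65e-08) and macrophage surface receptors (8 rose and 1 fell of 31, adjusted p = 5.51e-05). Cell cycle genes fell in 10 of 38 cases, with thymidine kinase Tk1 at -1.38 ± 0.24 and the replication inhibitor Gmnn at -1.35 ± 0.12 (adjusted p = 1.46e-16). The transcription factor gene Pax6 (-2.40 ± 0.44) was the lowest called gene with the same sign on all 6 arrays, and Aph1b, for a gamma-secretase subunit, stood at -1.86 ± 0.11. Sterol and fatty acid synthesis genes fell in 3 of 13 cases, with the desaturase Scd1 at -1.31 ± 0.38, but that group's shift was lost when gene correlation was estimated (adjusted p = 0.0517 with an estimated correlation).

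**Figure D2:**
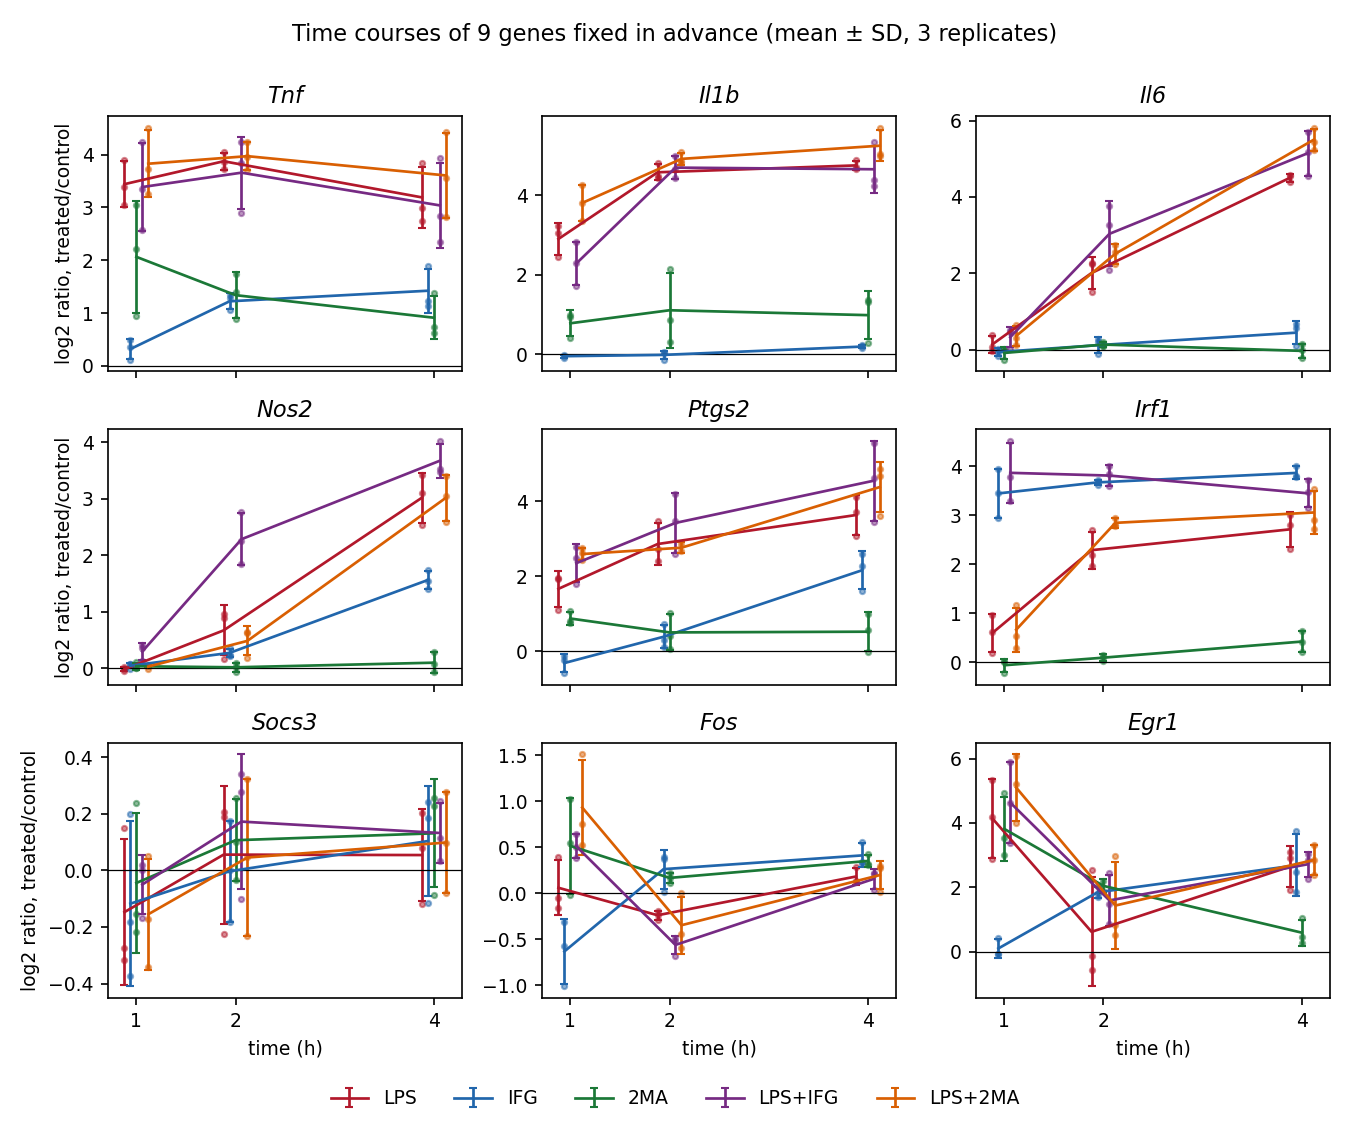
Log2 ratio of treated over control RNA (y axes) after 1, 2 and 4 h (x axes) for 9 genes chosen before the data were examined, with lines for the mean, bars for the SD and points for the 3 replicates of each treatment. Il6 and Nos2 rose after 1 h in every treatment with LPS, Irf1 was high from 1 h with IFG, and Socs3 and Fos were called in no treatment against control.

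Interferon gamma, a lymphocyte cytokine that primes macrophages, raised its known response genes from 1 h on. At 1 h Irf1 had already risen to 3.44 ± 0.50 and the immunity-related GTPase Irgm2 to 3.09 ± 0.15, while Myc fell to -1.43 ± 0.34. Interferon-gamma response genes rose in 11 of 28 cases at 1 h, 17 of 28 at 2 h and 20 of 28 at 4 h (adjusted p = 5.22e-66, 4.18e-72 and 3.82e-59). The antiviral list followed, with 6 of 35 higher at 1 h (7 adjusted over the list alone) and 22 at both later times. At 4 h the GTPases Tgtp1 (5.57 ± 0.27) and Gbp8 (5.01 ± 0.28), the chemokine Cxcl9 (4.90 ± 0.43) and the checkpoint ligand Cd274 (3.44 ± 0.47) were among the highest. Antigen processing genes rose in 4 of 22 cases, with Tap1 at 2.21 ± 0.13 and the immunoproteasome subunit Psmb10 at 1.73 ± 0.18 (adjusted p = 4.29e-16), and 8 of 23 NF-kB genes rose with Bcl3 at 2.00 ± 0.22 (adjusted p = 5.05e-15). The fractalkine receptor Cx3cr1 fell to -1.59 ± 0.19 and Esco2, needed for sister chromatid cohesion, to -1.48 ± 0.18. For the cell cycle list, 22 of 38 genes were lower by adjusted p alone with a median of -0.43 (adjusted p = 2.76e-17), all by less than 2-fold. Chemokines (3 of 16) and inflammatory cytokines (3 of 21) were higher at 4 h only with the preset correlation (adjusted p = 0.0579 and 0.0581 with an estimated correlation).

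Several immediate early genes rose with IFG at 4 h. Egr1 stood at 2.68 ± 0.97 after 0.10 at 1 h, Zfp36, which encodes an mRNA-destabilizing protein, was at 2.44 ± 0.57, and Ptgs2 at 2.16 ± 0.51, a gain of 2.47, SE 0.41 over 1 h. In all, 9 of 31 immediate early genes rose there (adjusted p = 1.44e-06, but 0.0823 with an estimated correlation), as did 5 of 30 cyclic AMP and CREB response genes (adjusted p = 6.69e-05) and 5 of 25 apoptosis regulators, with the death receptor Fas at 2.70 ± 0.17 (adjusted p = 1.67e-07). Nos2 reached 1.56 ± 0.17, beside 3.02 with LPS in a difference that was not tested. At 4 h 136 of the 196 features higher with IFG were higher with LPS too, and 12 of the 20 lower ones (31 without IFG replicate 2) were lower with both. The sizes of the sets alone give 7.13 and 0.234. The highest of 20 simulations of unchanged groups on shared control RNA gave 0. Unchanged features seldom reach 2-fold, so this 0 cannot show how much shared controls add. Part of the excess over the set sizes may come from control RNA that both treatments shared, and the 3 replicates were too few for separate controls.

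2MA, which acts on purine receptors, changed few features, 39 at 1 h (31 higher, 8 lower), 38 at 2 h (37 higher, 1 lower) and 17 at 4 h (13 higher, 4 lower). Among the highest genes at 1 h were the zinc finger factors Egr2 (4.40 ± 1.07) and Egr1 (3.81 ± 0.99), followed by the chemokine Ccl7 (2.67 ± 0.39), Myc (2.54 ± 0.42), Zfp36 (2.32 ± 0.80) and the calcineurin regulator Rcan1 (2.30 ± 0.46). Immediate early genes rose in 13 of 31 cases at 1 h and 8 of 31 at 2 h (9 adjusted over the list alone) (adjusted p = 8.56e-41 and 7.3e-30). At 4 h 1 of 31 rose (3 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation). Cyclic AMP and CREB response genes (4 of 30, adjusted p = 3.45e-14) and MAPK phosphatases and Sprouty inhibitors (3 of 9, adjusted p = 2.75e-05) were higher at 1 h as well. Tnf stood at 2.06 ± 1.06, while Il6 (-0.09 ± 0.15) and Nos2 (0.03 ± 0.06) were not called. With each probe tested on its own, the Ccl7 probe farthest from the gene's mean stood at -0.052 and -0.19 at 1 h and 2 h. The probes of Ccl7 therefore differ, and what the others measured lay on average above the gene's mean. Of the higher features, 24 of 31 at 1 h, 27 of 37 at 2 h and 11 of 13 at 4 h were higher with LPS too. The sizes of the sets alone give 0.318, 0.679 and 0.473. The highest of 20 simulations of unchanged groups with shared controls gave 0, but unchanged features seldom reach 2-fold, so this 0 cannot bound the part of shared controls. Shared control RNA may add to the overlap with LPS as well. The 2MA counts rested on single replicates. Without replicate 1 they were 17, 9 and 11 at 1, 2 and 4 h. Without replicate 2 they were 87 at 1 h (35 higher, 52 lower) and 37 at 4 h, and without replicate 3 the 4 h count was 35. Fitted on its own replicates alone, 2MA changed 14 features at 2 h and 9 at 4 h, and with scaled spread 27 at 4 h. Arrays with treated RNA in Cy5 gave 97, 60 and 50 at 1, 2 and 4 h, with 60, 21 and 34 of them lower, and those with it in Cy3 83, 95 and 66.

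At 4 h of 2MA the antiviral list was shifted up, with a median of 0.52 over 35 genes and 13 higher by adjusted p alone (adjusted p = 4.7e-25); 1 member, Ifit2 (1.09 ± 0.76, named after its value was seen), passed both criteria adjusted over the list alone. The NF-kB list was higher at 2 h (2 of 23) and 4 h (1 of 23; adjusted p = 6.03e-14 and 1.13e-09), and the cell cycle list lower at 4 h with a median of -0.15 (adjusted p = 4.34e-08). The heat shock and antigen processing lists, higher here with the preset correlation, were lower on the arrays with treated RNA in Cy5 alone, and the cell cycle list at 2 h was higher on those with treated RNA in Cy3 alone.

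The next question was what IFG adds to LPS, a pairing known as classical activation. LPS+IFG exceeded LPS alone in 72 features at 1 h, 101 at 2 h and 94 at 4 h, and was lower in 3, 8 and 25. Cxcl9 differed by 5.14, SE 0.19 at 1 h and Irf1 by 3.27, SE 0.26. At 2 h Nos2 differed by 1.61, SE 0.20 and the transcription factor Irf8 by 3.31, SE 0.22. Interferon-gamma response genes exceeded LPS in 13 of 28 cases at 1 h, 17 of 28 at 2 h (18 adjusted over the list alone) and 8 of 28 at 4 h (adjusted p = 1.17e-85, 1.27e-55 and 3.96e-21). The antiviral list exceeded LPS in 13 of 35 cases at 1 h (14 adjusted over the list alone) and 8 of 35 at 2 h. At 4 h the surface protein Ly6i (4.06, SE 0.24), the leukotriene receptor Ltb4r1 (2.95, SE 0.22), the apoptosis gene Pmaip1 (2.80, SE 0.26), the Fc receptor Fcgr3 (2.66, SE 0.22) and the activin antagonist Fst (2.65, SE 0.18) were higher than with LPS. The receptor Tlr2 (-1.74, SE 0.22), the helix-loop-helix inhibitor Id3 (-1.62, SE 0.23) and the sulfotransferase Tpst1 (-1.59, SE 0.24) were lower. The test compared 3 against 3 replicates. The labels list lipid binding protein (100 pM) for LPS alone but not for the combinations, which the comparison cannot separate from IFG. With the spread of the arrays scaled to be equal, 51 features differed at 4 h (44 higher, 7 lower), and without LPS replicate 3 there were 88 higher and 46 lower. The 3 lower at 1 h were 5 with a dye term, 1 with scaled spread, with treated RNA in Cy5 or in Cy3 alone or without LPS replicate 2 or LPS+IFG replicate 2, and 0 without LPS replicate 1. The 8 lower at 2 h were 5 without LPS replicate 1 or LPS+IFG replicate 1 and 4 without LPS replicate 2.

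Against control, LPS+IFG at 4 h had some of the highest ratios in Iigp1 (5.68 ± 0.22), Tgtp1 (5.62 ± 0.13), Gbp3 (5.59 ± 0.24) and Cd40 (5.44 ± 0.38), and the coagulation initiator F3 stood at 5.49 ± 0.03 at 2 h. Interferon-gamma response genes rose in 22 of 28 cases, antiviral genes in 30 of 35, antigen processing genes in 7 of 22 and inflammatory cytokines in 11 of 21 (adjusted p = 6.28e-32, 3.87e-39, 3.24e-09 and 3.02e-11). The cell cycle list fell in 13 of 38 cases, with the mitotic kinesin Kif20a at -1.55 ± 0.34 (adjusted p = 7.02e-18), and the sterol list in 4 of 13 (adjusted p = 0.000493). Cx3cr1 fell to -2.27 ± 0.69 and Pax6 to -2.79 ± 0.47. At 1 h 21 of 31 immediate early genes rose, with Egr2 at 4.79 ± 0.99, and Txnip fell to -2.25 ± 0.20.

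Whether LPS and IFG act independently was asked by testing the combination against the sum of the single log2 ratios. At 1 h 10 features departed, all above the sum (6 with scaled spread, 5 above and 1 below), and at 2 h 35 departed, 15 above and 20 below (45 with scaled spread, 4 above and 41 below). The 1 h count was 6 with complete values, 17 with a dye term on all 90 arrays, and 22 and 5 with treated RNA in Cy5 and in Cy3 alone. The 2 h count was 23 with complete values, 53 with the dye term, and 19 (10 above, 9 below) with only the compared conditions fitted. It was also higher with replicate sets as a block. At 4 h 160 departed, 27 above and 133 below. The 27 above were 12 with scaled spread, 17 with only the compared conditions fitted, 73 and 43 with treated RNA in Cy5 and in Cy3 alone, and 44 without LPS+IFG replicate 3. LPS alone is listed with lipid binding protein and the combination without it, which this departure cannot separate from IFG. Among the largest departures below additivity at 4 h were Gbp3 (-3.97, SE 0.32), Tgtp1 (-3.82, SE 0.43), Gbp8 (-3.68, SE 0.42) and the GTPase Igtp (-3.49, SE 0.31), all high with either stimulus alone. The single ratios of Gbp3 (sum 9.56) and Tgtp1 summed to more than the limit of the deposited ratios (6.64). A departure below 0 was therefore forced for both, and its size cannot be read as an effect of the combination. The sums of Gbp8 and Igtp are not given here, so the size of their departures is not read as such an effect either. Of the 133 below the sum, 23 had sums within 2-fold of that limit or above it. Members of the antiviral list lay below the sum in 22 of 35 cases (24 adjusted over the list alone, adjusted p = 1.26e-53) and interferon-gamma response genes in 13 of 28 (14 adjusted over the list alone, adjusted p = 1.42e-34). Above the sum stood Fst (2.42, SE 0.21), the retinoic acid carrier Crabp2 (2.38, SE 0.42) and Pmaip1 (1.80, SE 0.32; 1.24 and not called with scaled spread). Early departures above the sum at 1 h included Cxcl9 (2.67, SE 0.24; 1.92 and not called with scaled spread) and the monocyte chemokine Ccl12 (2.01, SE 0.28), and at 2 h Nos2 (1.35, SE 0.25; 1.05 and not called with scaled spread, nor with only the compared conditions fitted). By 4 h Nos2 lay below the sum, by less than 2-fold. Irf1 lay below the sum at 2 h (-2.15, SE 0.31) and 4 h (-3.13, SE 0.31). Both of its sums were below the limit of the deposited ratios but within 2-fold of it. The 1 h count was 5 without LPS replicate 1, 5 without LPS replicate 2, 6 without IFG replicate 3 and 6 without LPS+IFG replicate 3.

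**Figure D3:**
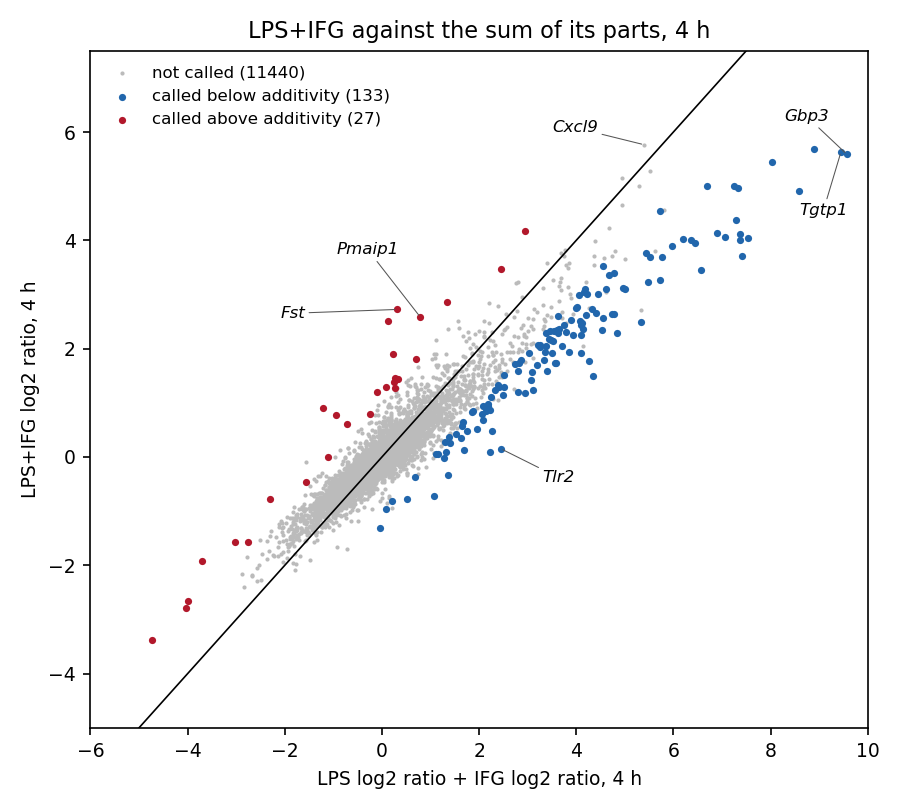
Mean log2 ratio of LPS+IFG (y axis) against the sum of the mean log2 ratios of LPS and of IFG (x axis) at 4 h, with a point for each feature and a line where both are equal. The 133 features called below additivity in blue have a median sum of 3.58, with Gbp3 at the highest sum among them, and 27 were called above it in red.

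LPS with 2MA was compared with LPS alone to see what a purine receptor agonist adds. LPS+2MA exceeded LPS in 8 features at 1 h, 3 at 2 h (11 with replicate sets as a block) and 13 at 4 h. In either direction 233, 519 and 642 of 11600 features had a limma unadjusted p under 0.05 at 1, 2 and 4 h. A share of 0.05 is expected there by chance, so these counts alone do not show further changes. Limma called none lower than LPS, with 7 lower at 4 h by adjusted p alone. However, 1 was called lower at 4 h with zeros kept as 0 or without LPS replicate 3, and 1 at 2 h without LPS+2MA replicate 1. The 4 h count was 3 with scaled spread, 3 with only the compared conditions fitted and 5 with treated RNA in Cy5 or in Cy3 alone. A dye term on all 90 arrays gave 15, 12 and 21 at 1, 2 and 4 h, Cy3 alone 3 at 1 h and zeros kept as 0 gave 5 at 2 h. Acp5, which encodes the tartrate-resistant acid phosphatase of osteoclasts and macrophages, was higher at every time, by 1.43, SE 0.17 at 1 h, 1.36 at 2 h and 1.51, SE 0.17 at 4 h (adjusted p = 3.59e-06, 1.4e-05 and 2.33e-06). Its log2 ratio was 1.70, 1.95 and 2.42 with LPS+2MA, 0.27, 0.59 and 0.91 with LPS and 0.14, 0.30 and 0.33 with 2MA. Tslp, a cytokine gene, was higher by 1.06 at 2 h and 1.32, SE 0.19 at 4 h, the cyclin Ccnd2 by 1.79, SE 0.31 and the Wnt inhibitor Dkk2 by 1.43, SE 0.24 at 4 h (Dkk2 1.18 and not called with scaled spread). With only the compared conditions fitted, Acp5, Ccnd2 and Dkk2 were not called at 4 h. Besides Acp5 and Tslp, the third feature at 2 h was a probe without a gene name, and the values at 2 h were chosen after they were seen. Immediate early genes exceeded LPS in 2 of 31 cases at 1 h (5 adjusted over the list alone, adjusted p = 2.93e-17). List shifts at 2 h and 4 h were lost with an estimated correlation (immediate early at 2 h adjusted p = 0.171, NF-kB at 4 h adjusted p = 0.0859 with an estimated correlation). The 1 h count was 3 without LPS replicate 1, without LPS replicate 2 or without LPS+2MA replicate 2. The 2 h count was 6 without LPS+2MA replicate 1 and 5 without LPS+2MA replicate 3, and the 4 h count 7 without LPS replicate 2. Lipid binding protein is listed for LPS alone here too.

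Against control, LPS+2MA at 1 h raised 23 of 31 immediate early genes, with Egr2 at 5.40 ± 0.96 and Dusp1 at 4.84 ± 0.40, and 5 of 9 MAPK phosphatases and Sprouty inhibitors (adjusted p = 8.68e-88 and 5.82e-16). Txnip fell to -2.42 ± 0.02. The type I interferon gene Ifnb1 stood at 4.86 ± 0.40 at 2 h and 4.67 ± 0.61 at 4 h. At 4 h Cmpk2 (5.74 ± 0.27), Ifit2 (5.55 ± 0.23) and Il6 (5.50 ± 0.29) were among the highest, and 32 of 35 antiviral genes, 21 of 28 interferon-gamma response genes and 16 of 21 inflammatory cytokines rose (adjusted p = 1.2e-44, 4.6e-25 and 1.61e-16). Cell cycle genes fell in 11 of 38 cases, with the ribonucleotide reductase subunit Rrm2 at -1.46 ± 0.43, and sterol synthesis genes in 4 of 13, with the squalene epoxidase Sqle at -1.39 ± 0.15 (adjusted p = 8.83e-16 and 4.73e-05).

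Departures of LPS+2MA from the sum of LPS and 2MA numbered 1 feature at 1 h (more with replicate sets as a block), 1 at 2 h (10 with the block) and 6 at 4 h (13 with the block) by limma. These counts rest on the setting. At 1, 2 and 4 h they were 10, 13 and 10 with a dye term on all 90 arrays, 2, 0 and 1 with only the compared conditions fitted, and 9, 0 and 37 with treated RNA in Cy5 alone. Cy3 alone gave 2 and 5 at 1 h and 2 h, each probe on its own 2 and 2, scaled spread 0 and 3 at 2 h and 4 h, and zeros kept as 0 gave 10 at 4 h. LPS alone is listed with lipid binding protein and the combination without it, which this departure cannot separate from 2MA. At unadjusted p under 0.05 there were 254, 294 and 404 of 11600 features, below the share of 0.05 expected by chance. At 1 h the feature called was Acp5, above the sum (1.29, SE 0.21, limma adjusted p = 0.00552), and at 2 h Ccl7, below the sum (-1.77, SE 0.28, adjusted p = 0.00236). With each probe tested on its own, the Ccl7 probe farthest from the gene's mean departed by 0.076 at 2 h. Without LPS+2MA replicate 2, Acp5 at 1 h was 1.18 and not called, nor was it with Cy3 alone or only the compared conditions fitted. Ccl7 was not called with scaled spread (-2.09), with Cy5 alone (-1.79) or with only the compared conditions fitted. At 4 h Tslp (1.28, SE 0.23) and Acp5 (1.18, SE 0.21) lay above the sum, and the membrane protein Tmem98 (-1.38, SE 0.21), ornithine decarboxylase Odc1 (-1.30) and the adaptors Stap1 (-1.18, SE 0.18) and Samsn1 (-1.06) below it. Of these, Acp5 was not called at 4 h without LPS replicate 2 (1.07), 2MA replicate 2 (1.04), LPS+2MA replicate 1 (1.03) or LPS+2MA replicate 2 (1.12). Odc1 was not called without LPS replicate 2 (-1.32), 2MA replicate 1 (-1.01), LPS+2MA replicate 1 (-1.21) or LPS+2MA replicate 2 (-1.25), nor Samsn1 without LPS replicate 2 (-0.93) or LPS+2MA replicate 3 (-0.95). These 3 were not called with scaled spread either (0.87, -1.30 and -0.91), nor was Samsn1 with Cy5 alone or Acp5 with Cy3 alone. With only the compared conditions fitted, Tslp alone was called at 4 h. No list shift held with an estimated correlation (immediate early genes at 1 h adjusted p = 0.487, antiviral genes at 4 h adjusted p = 0.602). The count at 1 h was 2 without LPS replicate 2, 2 without 2MA replicate 3 and 0 without LPS+2MA replicate 2. At 2 h it was 2 without LPS replicate 1, 3 without 2MA replicate 1, 3 without 2MA replicate 3 and 2 without LPS+2MA replicate 3, and at 4 h it was 3 without LPS replicate 2.

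Change over time was tested as the 4 h ratio less the 1 h ratio of each treatment. It differed from 0 in 426 features with LPS (319 higher and 107 lower at 4 h), 145 with IFG (128 and 17), 17 with 2MA (5 and 12), 553 with LPS+IFG (360 and 193) and 595 with LPS+2MA (414 and 181). With LPS, Cmpk2 gained 5.41, SE 0.33 and Ifit2 5.27, SE 0.48, while Egr2 changed by -3.18, SE 0.65 and the antiproliferative gene Btg2 by -3.16, SE 0.41. Antiviral genes were higher at 4 h in 31 of 35 cases with LPS, 23 of 35 with LPS+IFG and 31 of 35 with LPS+2MA, and interferon-gamma response genes in 14 of 28 with IFG. Immediate early genes were lower at 4 h in 11 of 31 cases with LPS (adjusted p = 0.075 with an estimated correlation) and 14 of 31 with LPS+IFG (15 adjusted over the list alone, adjusted p = 0.0541 with an estimated correlation). They were lower in 17 of 31 with LPS+2MA (18 adjusted over the list alone, adjusted p = 6.2e-10) and 6 of 31 with 2MA (9 adjusted over the list alone, adjusted p = 1.42e-15). With IFG, Gbp8 gained 3.88, SE 0.34 and Cd40 2.81, SE 0.34, and 4 of 22 antigen processing genes were higher at 4 h (adjusted p = 7.07e-16). With LPS+IFG Il6 gained 4.82, SE 0.27 and the anticoagulant receptor Procr 4.08, SE 0.24. Cell cycle genes were lower at 4 h in 4 of 38 cases with LPS, 12 of 38 with LPS+IFG and 10 of 38 with LPS+2MA (adjusted p = 1.57e-15, 4.09e-19 and 2.5e-16). The 2MA count was 4 without the 1 h replicate 1, 5 without the 4 h replicate 1 and 26 without the 4 h replicate 3 (15 higher, 11 lower), and 11 (6 higher, 5 lower) with scaled spread. It was 1 with only the compared conditions fitted, 35 with a dye term on all 90 arrays and 9 with treated RNA in Cy3 alone, and the LPS+IFG count was 295 with scaled spread.

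No shift of the purine receptor and nucleotide metabolism list or the eicosanoid list was called against control, although 12 and 15 single tests over the 15 conditions were, among them the purine nucleoside phosphorylase Pnp at 2.23 ± 0.24 with LPS at 4 h. The glycolysis and hypoxia list, the lipid efflux list, the oxidative stress list and the lysosomal list had 3, 4, 23 and 5 called tests against control and the heat shock list 15. Their shifts did not hold with an estimated correlation, the lowest adjusted p = 0.139, 0.0809, 0.0835, 0.241 and 0.191. Single members changed all the same, such as Gclc, for glutathione synthesis, at -1.41 ± 0.12 and the superoxide dismutase Sod2 at 1.56 ± 0.04 with LPS at 4 h, and the scavenger receptor Msr1 at 1.57 ± 0.37. Markers of fibroblasts, lymphocytes, epithelial cells and erythroid cells gave 0 called tests against control by limma, with 6, 13, 14 and 7 at unadjusted p under 0.05 of 150, 135, 120 and 60. The reference genes gave 0 called tests against control of 120, with 13 at unadjusted p under 0.05, and 1 of 8, the polymerase subunit gene Polr2a, fell in LPS+2MA between 1 h and 4 h (-1.04), a gene named after its value was seen.

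**Figure D4:**
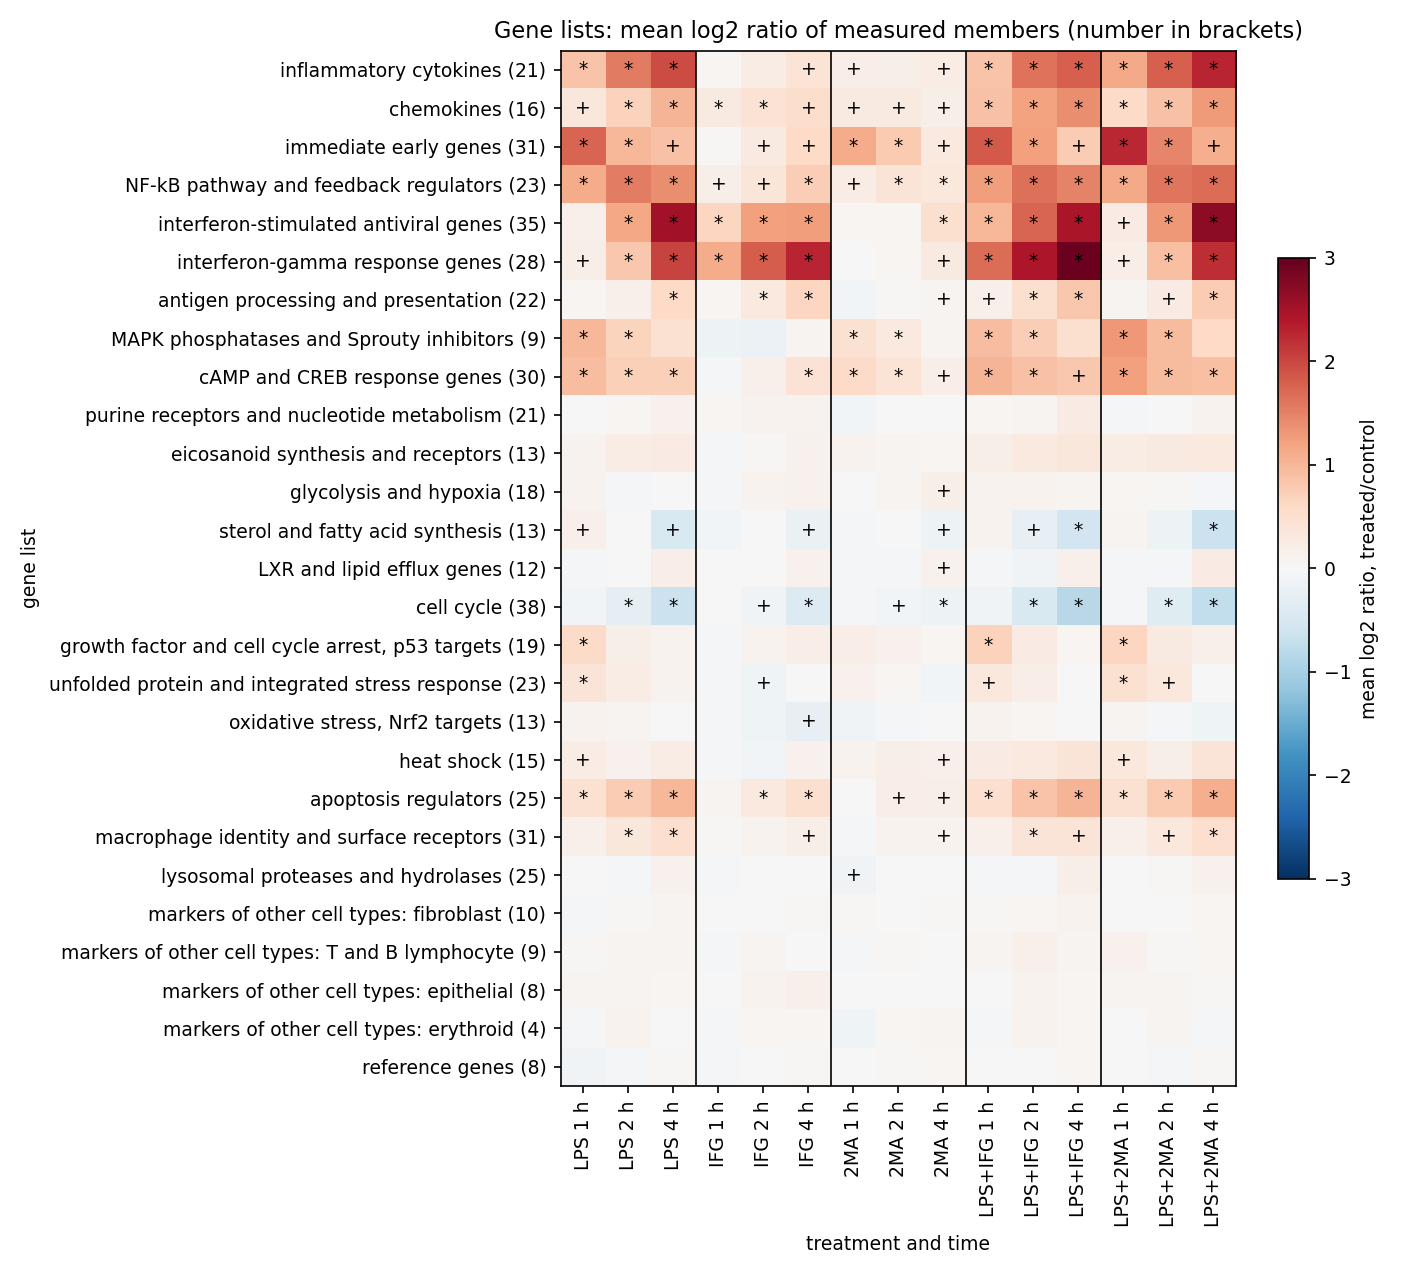
Mean log2 ratio over the measured members of each gene list (rows, number measured in brackets) in each treatment and time (columns), on a color scale from -3 to 3, with * for shifts called with the preset and an estimated correlation and + for those called with the preset alone. The antiviral and interferon-gamma lists are highest at 4 h in every treatment with LPS, and the cell cycle list is below 0 there.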

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

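The tests for endotoxin in the interferon, for control RNA shared by all treatments and for saturation among genes that read lower with both stimuli were chosen after the results were seen. Effects of the same treatment that differed between groups were singled out in 11 comparisons. The combination differed from the sum of its parts in 10, 35 and 160 features for LPS+IFG at 1, 2 and 4 h and in 1, 1 and 6 for LPS+2MA. The 4 h effect differed from the 1 h effect in 426 features with LPS, 145 with IFG, 17 with 2MA, 553 with LPS+IFG and 595 with LPS+2MA.

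Other groupings of the replicates were too few for a share under 0.05: 4 sign patterns of the 3 sets for ratios against 0 and additivity, and 10 splits of 6 replicates elsewhere. In each comparison the real grouping alone (1 of 4 or 1 of 10) gave as many features, except that 2 of 10 splits did so for 2MA at 4 h against 1 h, where another split gave 30 against the real 17. The real count and the highest of the others were 125 and 2, 256 and 3, and 558 and 8 with LPS at 1, 2 and 4 h, 43 and 0, 125 and 2, and 216 and 4 with IFG, and 39 and 3, 38 and 0, and 17 and 1 with 2MA. They were 215 and 8, 433 and 1, and 778 and 6 with LPS+IFG, and 142 and 3, 322 and 1, and 763 and 14 with LPS+2MA. Against LPS they were 75 and 1, 109 and 0, and 119 and 9 for LPS+IFG, and 8 and 0, 3 and 1, and 13 and 4 for LPS+2MA; among the 4 splits that part all 3 sets, those other than the real one gave 0. For additivity they were 10 and 1, 35 and 0, and 160 and 0 with LPS+IFG, and 1 and 0, 1 and 0, and 6 and 0 with LPS+2MA. Over time they were 426 and 3 with LPS, 145 and 0 with IFG, 553 and 5 with LPS+IFG, and 595 and 1 with LPS+2MA.

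The first pattern weighed was the 133 features below additivity for LPS+IFG at 4 h, with a median departure of -1.44. The upper limit of the deposited ratios is argued against for 105 of them, whose single ratios summed to less than 5 on the log2 scale. The limit there is 6.64. It cannot be told apart for 23 features, whose sums lay within 2-fold of the limit or above it (highest 9.56). A combination cannot reach a sum above the limit, so a departure below 0 was forced there. Saturated spots cannot be told apart for the whole set: 47 read over 0.5 lower with both stimuli than with the higher single one, which a ceiling would not give, while 76 lay within 0.5 of it. Of those 47, 44 passed the moderated test of that difference, but they were picked for it, so saturation cannot be told apart there either. LPS and IFG acting on the same genes is a candidate explanation, and it stays a hypothesis formed on these data. Of the 133, 85 were raised by both alone. The departure subtracts both single ratios and so favours features high in both, which means that this share cannot decide. The design also does not separate this explanation from lipid binding protein, listed for LPS alone.

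A further pattern was the exact zeros, which were treated as missing ratios. Dim spots are argued against for probes of ribosomal protein genes, whose transcripts are abundant. These 61 probes held zeros in 34.1% of values against 5.31% of other probes. The highest of 1000 random sets of 61 probes had 14.5%. They are few of the 13461 probes that name a single gene, so dim spots cannot be told apart for the rest. A Cxcl9 probe, for example, was at 0 with LPS at 1 and 2 h, where another Cxcl9 probe stood at 0.026 and 0.147. Spots too bright in treated RNA are argued against as a general cause. Where a probe was at 0 in a condition, other probes of its gene had a median log2 ratio of 0.078 (70 values from 40 genes). Of the 70, 20 lay above 1 and 0 lay as far below 0, so spots too bright in treated RNA cannot be told apart for those 20. Zeros at abundant transcripts may still point to spots too bright in both channels, which was not tested. No biological explanation was tested.

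The last pattern was the 136 features raised by both LPS and IFG at 4 h. Control RNA shared by all treatments is argued against as the whole cause. Over these features the median ratio with 2MA at 4 h was 0.442 (upper quartile 0.691), while the lower of their LPS and IFG ratios had a median of 1.49. The features were chosen for LPS and IFG ratios of at least 2-fold and not for 2MA, so part of this gap was fixed in advance. Control RNA shared by LPS and IFG but not 2MA cannot be told apart, as simulated unchanged features seldom reach 2-fold and shared 0 at most in 20 simulations. Endotoxin in the interferon cannot be told apart: over the 119 features LPS raised at 1 h the median IFG ratio was 0.009 at 1 h (upper quartile 0.231), which goes against it, but 0.574 at 4 h, which goes with it. Whether these are genes that LPS reaches late cannot be told either: 102 of the 136 were not raised by LPS at 1 h, but neither were 243 of the 286 that LPS and not IFG raised at 4 h.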

How the results depend on the processing

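Zeros kept as 0 and averaging before the filter were tested only after the data were seen, the other alternatives were planned, and where no reason is given the cause was not tested. The number of features called was within 1.5 times its main value in all 32 comparisons with array median centring (11600 features tested), no filter on missing values (12518) and averaging before the filter (11614). Of 724 values of named genes, 722, 713 and 714 stayed on the same side of the threshold there.

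Scaling to equal spread moved 10 counts: IFG 1 h to 74, 2MA 4 h to 27, LPS+IFG 4 h to 474, LPS+IFG against LPS 4 h to 51, LPS+2MA against LPS 4 h to 3, additivity of LPS+IFG 1 h to 6 and of LPS+2MA 2 h and 4 h to 0 and 3, and 4 h against 1 h to 11 with 2MA and 295 with LPS+IFG. It turned 3 list shifts: antiviral genes for additivity of LPS+IFG 1 h (adjusted p = 0.967), and the NF-kB list over time with LPS (0.466) and LPS+IFG (0.956). With treated RNA in Cy5 alone, counts moved to 75 for IFG 1 h, 97, 60 and 50 for 2MA at 1, 2 and 4 h, 5 for LPS+2MA against LPS 4 h, 22 for additivity of LPS+IFG 1 h and 9, 0 and 37 for that of LPS+2MA at 1, 2 and 4 h, and the antigen processing and heat shock lists turned in 2MA 4 h (both 0.982). With Cy3 alone they moved to 80 for IFG 1 h, 83, 95 and 66 for 2MA, 3 and 5 for LPS+2MA against LPS at 1 h and 4 h, 5 for additivity of LPS+IFG 1 h, 2 and 5 for that of LPS+2MA at 1 h and 2 h and 9 for 2MA over time, and the cell cycle list turned in 2MA 2 h (0.974). A single orientation leaves each probe's dye bias in ratios against 0. In the simulated data for LPS 4 h, to which a dye bias had been added, it gave 49 and 38 false calls with Cy5 and Cy3. Both orientations together gave 0. The spread of that added bias was chosen by hand, so these counts do not measure the bias of the real probes.

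Fitting only the compared conditions, with fewer replicates behind each variance, moved 2MA 2 h to 14 and 4 h to 9, LPS+2MA against LPS 4 h to 3, additivity of LPS+IFG 2 h to 19 and of LPS+2MA to 2, 0 and 1 at 1, 2 and 4 h, and 2MA over time to 1. All 90 arrays with a dye term gave 15, 12 and 21 for LPS+2MA against LPS, 17 and 53 for additivity of LPS+IFG 1 h and 2 h, 10, 13 and 10 for that of LPS+2MA, and 35 for 2MA over time. The replicate block gave 11 for LPS+2MA against LPS 2 h, 54 for additivity of LPS+IFG 2 h, 7, 10 and 13 for that of LPS+2MA at 1, 2 and 4 h, and 31 for 2MA over time. Zeros kept as 0 gave 5 for LPS+2MA against LPS 2 h and 10 for additivity of LPS+2MA 4 h, and turned the chemokine shift in additivity of LPS+IFG 1 h (0.971). Complete values, with 8708 features tested, gave 6 and 23 for additivity of LPS+IFG 1 h and 2 h. Every probe on its own gave 2 and 2 for additivity of LPS+2MA 1 h and 2 h. The probes of Ccl7 differ, and the one farthest from the gene's mean turned its sign. It stood at -0.052 and -0.19 in 2MA 1 h and 2 h, -0.0032 in LPS+2MA against LPS 1 h and 0.076 in additivity of LPS+2MA 2 h. An estimated correlation left 172 of 298 list shifts, and the other settings called 264 to 325.

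Leaving out each replicate gave 17 to 87, 9 to 53 and 11 to 37 for 2MA at 1, 2 and 4 h, 3 to 8, 2 to 6 and 7 to 11 for LPS+2MA against LPS, 5 to 9 for additivity of LPS+IFG 1 h, 0 to 2, 1 to 3 and 3 to 8 for that of LPS+2MA, and 4 to 26 for 2MA over time; the remaining 21 counts stayed within 1.5 times.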

Other observations

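The genes in the next paragraph were chosen after their values were seen, and the test of 2MA targets in the last was planned before its result was seen, while its form on held-out sets was added after. Values are means over the replicates that had one.

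Of the listed genes, 63 lacked values in too many replicates to enter the comparisons, and several strong responders were among them, so the counts understate the induced sets. Cxcl10, a chemokine induced by interferons, had log2 ratios of 3.23 ± 0.51 with LPS and 3.44 ± 0.31 with IFG at 1 h (n = 3) and no usable mean with LPS at 4 h. Cxcl11, its relative, stood at 2.42 ± 0.36, 3.72 ± 0.36 and 4.68 ± 0.50 with IFG at 1, 2 and 4 h (n = 3) and at 4.42 ± 0.28 with LPS at 4 h (n = 3). Gbp2 reached 5.18 ± 0.42 with IFG at 2 h and 5.10 ± 0.58 with LPS at 4 h (n = 3). The neutrophil chemokine Cxcl2 stood at 4.49 ± 0.69 with LPS at 1 h (n = 2) and 3.08 ± 0.91 with 2MA at 1 h (n = 2), and at -1.09 ± 0.76 with IFG at 1 h (n = 3). The NF-kB inhibitor Nfkbia was at 1.97 ± 0.07 with LPS at 1 h (n = 2). The alarmin Il33 was at 2.70 ± 0.65 with LPS+2MA at 4 h (n = 3) and 1.42 ± 0.50 with LPS+IFG (n = 2), beside 0.42 ± 0.06 with LPS (n = 2); the difference was not tested.

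Genes that 2MA raised on its own were followed into LPS+2MA at 1 h. Over the 31 features raised by 2MA, the median departure from additivity was -0.813 (quartiles -1.402 and -0.422), with medians of 1.75 for 2MA, 2.57 for LPS and 3.31 for LPS+2MA. The features were chosen for a high 2MA ratio, which the departure subtracts, so this value is pushed below 0 and cannot decide by the planned bound of 0.5. When the features were chosen on the other sets, the held-out departures were -1.36, -0.669 and -0.308 in sets 1, 2 and 3, the last short of that bound. Whether 2MA acts on its targets in the same way with LPS as without therefore cannot be told. LPS also raised 24 of the 31, and 29 were still raised in LPS+2MA.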
